A study of Saccharomyces cerevisiae with 37 samples.

How the data were processed

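The series measured RNA levels on Affymetrix Yeast Genome 2.0 arrays in 37 samples of 4 yeast cultures. Cells of strain Y262 were grown to mid-log phase at 26 °C and transcription was stopped by adding an equal volume of medium at 49 °C, which brought the culture to 37 °C, per the labels' protocols. RNA was copied from poly-T primers and biotin-labelled (same protocols), so a change in poly(A) tail length could change the signal at constant transcript. The labels name 25 and 40 min of pretreatment, read in the order in which the 2 stresses are named. The labels describe the arrays at time 0 as technical replicates, and no arrays of reference 2 after 30 min were used. Nothing in the labels gives a batch.

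The authors deposited log2 values per probe set made by RMA, per the submitters' processing notes. Its version, and whether all arrays were normalized together, are not given in the sources used here. The deposited values run from 3.69 to 17.5 over 5900 probe sets, and array medians lie between 10.5 and 12.9. The 18 probe sets of bacterial poly-A spike-ins fell with time by a median of 0.072 to 0.095 log2 per 10 min in the 4 cultures, less than the median gene (0.29 to 0.40), so the values were read as scaled to spike-ins, though not fully. That step is inferred, not stated. The level of a whole array therefore rests on a few control probe sets, and an error in them moves all genes of an array together.

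Probe sets were named with the platform's annotation: 5498 had 1 gene, 0 had several and 402 were unnamed (137 control, 47 reporter and 218 other probe sets). All 5498 identifiers matched a table of yeast genes, 12 symbols were updated, and 5449 genes resulted, each represented by its brightest probe set. No genome was used, so no coordinates are given. For 62 genes the probe set also matches another gene copy. Genes were tested where their mean over the 28 arrays at 0 to 30 min was above 11.04, the 30th percentile of all probe sets, which left 3899. A filter on probe sets of no yeast gene had been preferred but needed 500 of them, and 218 were left.

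Each culture was summarised by 1 value per gene: the level at time 0 (mean of its 2 arrays) and the least-squares slope over the 6 time points from 0 to 30 min, in log2 per 10 min. The culture, not the array, was the replicate. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) fitted the 4 cultures, with Benjamini-Hochberg adjustment at a threshold of 0.05 in 7 comparisons: level and slope of oxidative stress against reference, DNA damage against reference and oxidative stress against DNA damage, and the reference slope against the median gene. The 2 references gave 1 residual degree of freedom, and the stressed cultures were assumed to vary like them. The prior degrees of freedom of eBayes were 235 for levels and infinite for slopes as deposited, 5.46 and 2.43 on centred arrays, and 3.51 for reference decay. The design had assumed arrays scaled alike by RMA; the values are not, and slopes as deposited were kept as the main values with centred arrays beside them.

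The 19 gene lists, from textbook knowledge, covered cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, RNA polymerase I and III, the proteasome, antioxidant defence, the pentose phosphate pathway, general stress, chaperones, the DNA damage response, sulfur and Gcn4-controlled amino acid metabolism, glycolysis, oxidative phosphorylation, translation factors, ergosterol synthesis, histones, cell cycle regulators and mRNA decay. They were tested with camera at a preset correlation of 0.01 where at least 5 members were tested. A second run estimated the correlation from arrays. Further lists for iron, mating, hypoxic and purine genes were written after the data were seen. The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. That rule takes, per comparison, up to 10 genes with the largest rise and 10 with the largest fall among those called with the same sign against each reference, the 3 leading members of each list that passed, and 10 fixed genes (RPO21, TRX2, TSA2, CTT1, HSP12, RNR3, HUG1, MAG1, RPL3 and NOP56).

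The relation of level and slope changes was described with independent arrays and references. Values expected from shared references without effects came from 100 simulations. The scripts were tested on simulated data with 200 changed genes. For the level, differences of 1, 1.5 and 2 log2 were recovered in 55%, 100% and 100% of genes for oxidative stress and 50%, 97.5% and 100% for DNA damage. For the slope, 0.4, 0.6 and 0.8 log2 per 10 min were recovered in 37.5%, 75% and 100% for oxidative stress and 17.5%, 65% and 100% for DNA damage. False calls numbered 6, 4, 6 and 4 in these runs. For reference decay, 200 genes changed by −0.6 were recovered in 100%, with 30 false calls, more than the threshold of 0.05 allows for. Alternatives were array centring, quantile normalization, the filter, the choice of probe set, an intensity trend in the prior, the scatter of arrays as the error, leaving out each reference, time point or time 0 array, other time windows, and settings added after the data were seen (centred arrays with their scatter as the error, camera with an estimated correlation on them, the reference of the same spike-in pattern, and the relation without rising genes). Under quantile normalization some of the brightest genes took equal values in the 2 references, and limma moved their zero variances off 0. Figures were drawn with matplotlib 3.10.9.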

Results

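Transcript levels were followed after transcription was stopped in budding yeast (Saccharomyces cerevisiae) strain Y262, which carries a temperature-sensitive RNA polymerase II. Cells grew in rich medium at 26 °C and were moved to 37 °C at time 0. There were 4 cultures: 2 references without added stress, 1 kept in 0.3 mM hydrogen peroxide for 25 min before the shift (oxidative stress), and 1 kept in 0.1% methyl methanesulfonate, a DNA-alkylating agent, for 40 min before it (DNA damage). Arrays were taken at 0, 5, 10, 15, 20 and 30 min in all 4 cultures, with 2 technical arrays at time 0, and at 40, 50 and 60 min in 3 of them. Later arrays of reference 2 were not used. The 37 arrays were 10, 7, 10 and 10 for reference 1, reference 2, oxidative stress and DNA damage. Each stress had 1 culture, so the spread between the 2 references was the only biological spread measured, and culture number limits every value's precision.

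The median of the 3899 genes tested fell in every culture. Its level at time 0 was 13.03 (log2) in reference 1, 12.86 in reference 2, 13.33 under oxidative stress and 12.89 under DNA damage. The median slope over 0 to 30 min was −0.40, −0.30, −0.29 and −0.32 log2 per 10 min in the same order, and the half-life of the median gene was 25.2, 33.2, 34.4 and 30.8 min. The bacterial spike-in probe sets fell as well, by a median of −0.095, −0.091, −0.094 and −0.072 log2 per 10 min, and this part was not taken off the slopes and half-lives. Technical arrays at time 0 were offset by a median of 0.46, 0.13, 0.36 and 0.018, with an SD over genes of 0.060 to 0.087. Across genes, the time 0 levels of the references correlated at r = 0.970 and their slopes at r = 0.890. RPO21 encodes the large subunit of RNA polymerase II. Relative to the median gene it stood at −0.044 at time 0 under oxidative stress and −0.16 under DNA damage. The test, run on its values as deposited, called it in neither stress.

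**Figure D1:**
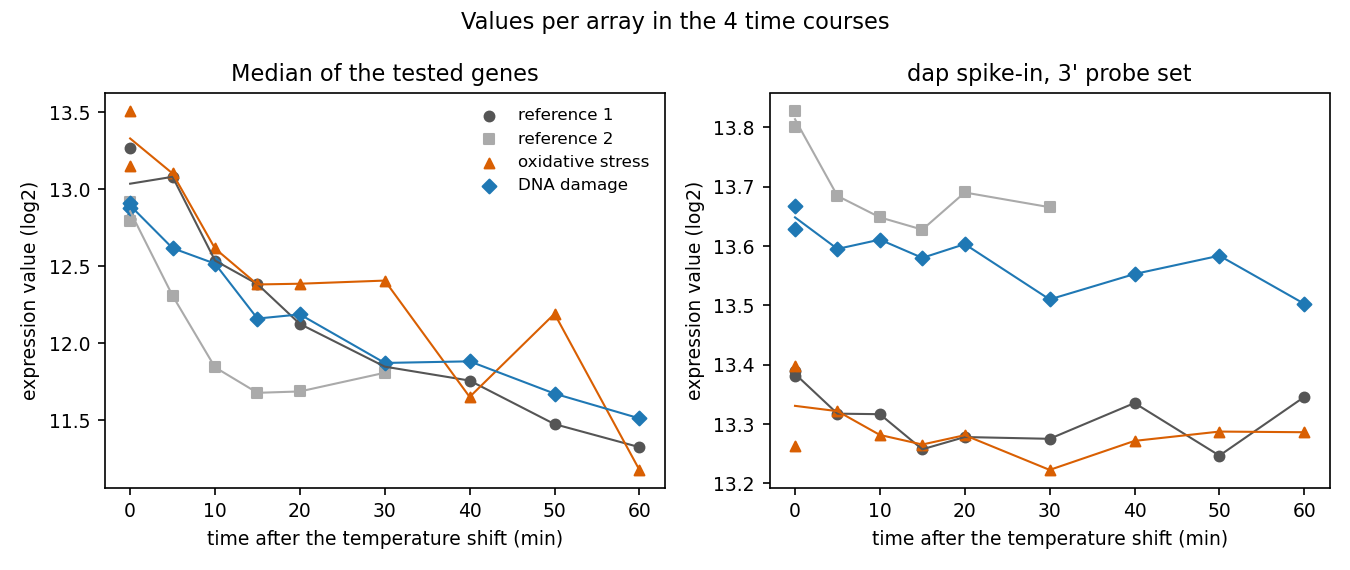
Median log2 value of the tested genes (left) and log2 value of a bacterial dap spike-in probe set (right) per array against time after the temperature shift, 1 point per array, lines through the mean per time point. The gene median fell in all 4 cultures, while the spike-in averaged 13.31 in reference 1, 13.71 in reference 2, 13.29 under oxidative stress and 13.58 under DNA damage.

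The dap, thr and phe spike-in probe sets split the cultures into pairs. Over these, oxidative stress lay within a mean of 0.065 log2 of reference 1 and DNA damage within 0.089 of reference 2. Other pairs differed by 0.20 to 0.24. The mean of all poly-A spike-ins did not pair them so. At 30 min it was 11.49, 11.57, 11.54 and 11.46 (reference 1, reference 2, oxidative stress, DNA damage). The labels give no batch, so values against the reference of the same spike-in pattern stand beside the main ones: reference 1 for oxidative stress, reference 2 for DNA damage, and the difference of these for the direct comparison. The all-gene median differed from the references by 0.29 at time 0 under oxidative stress (0.20 against reference 1, 0.39 against reference 2) and by −0.15 under DNA damage (−0.22 and −0.070). Reference 1 lay 0.15 above reference 2. Level differences below are therefore relative to the median gene of their comparison, while tests were run on values as deposited. The oxidative stress culture also stood apart in 5.8S ribosomal RNA. This control probe set averaged −1.64 relative to the median probe set of its arrays (−2.11 to −1.30 over 10 arrays), against 0.64, 0.37 and 0.068 in reference 1, reference 2 and DNA damage, and every oxidative stress value below comes from that culture.

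With the scatter of arrays as the error, the test of gene lists passed 8 of 19 lists in level and 7 in slope between reference 1 and reference 2. For oxidative stress, DNA damage and the direct comparison it passed 9, 11 and 11 in level and 7, 8 and 9 in slope. The same fit called 292 genes in level between the references, and on centred arrays 2598 in level and 56 in slope.

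FRM2, SRX1, TSA2 and OYE3 rose most under oxidative stress at time 0. FRM2 (YCL026C-A), of the nitroreductase family, stood 47.1-fold above the references relative to the median gene (log2 5.56, standard error 0.29, 1 stressed against 2 reference cultures, adjusted p = 2.0e-50), and SRX1 (YKL086W), the sulfiredoxin that repairs oxidised peroxiredoxins, 46.0-fold (log2 5.52). The peroxiredoxin gene TSA2 (YDR453C) rose 34.0-fold and OYE3 (YPL171C), an NADPH oxidoreductase, 29.0-fold. In both references these 4 genes lay below the expression filter of 11.04, where array values flatten, so their folds are not exact. The catalase gene CTT1 rose 8.47-fold (log2 3.08, adjusted p = 4.1e-23), and the small heat shock gene HSP12 2.56-fold (adjusted p = 1.1e-06). UTR2, a cell wall transglycosylase gene, showed the largest fall (log2 −1.64, adjusted p = 1.0e-04), and RNR1, the large subunit of ribonucleotide reductase, also fell (−1.46, adjusted p = 0.00117).

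Other genes with the largest rises were HBN1 (log2 4.42), DDR2 (4.24), the glutathione transferase genes ECM4 (4.17) and GTT2 (3.94), HSP30 (4.10), a membrane heat shock gene, and AAD6 (4.02). Falls followed UTR2 in ATF2 (−1.63), ANB1 (−1.59), CYB5 (−1.51), ATO3 (−1.50), FAR1 (−1.43), TEC1 (−1.35), HMG1 (−1.33) and PRM1 (−1.32). Against reference 1 alone the difference of FRM2 was 5.74 and that of SRX1 5.75, but that of ANB1, an eIF5A gene expressed at low oxygen, was −0.46 against −2.73 from reference 2. FAR1 and PRM1, genes of the mating response, stood at −0.88 and −0.74 against reference 1. The thioredoxin gene TRX2 rose by 0.54 (adjusted p = 0.0353) and the DNA glycosylase gene MAG1 by 1.41 (adjusted p = 3.6e-07). RPL3 stood at −0.0023 (adjusted p = 0.567) and NOP56 at −0.063 (adjusted p = 0.648). Of the 458 genes called higher, 22 lay below the filter in both references, AAD6 among them, and 43 in at least 1, CTT1 and DDR2 among them.

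Of the 19 gene lists fixed in advance, 3 rose at time 0 under oxidative stress, in the culture with 5.8S ribosomal RNA at −1.64. Of 41 general stress genes, targets of the transcription factors Msn2 and Msn4, 32 rose, 0 fell and 9 did not pass (34 rose and 0 fell adjusted over the list alone). The median shift was 1.07 against reference 1 minus reference 2 of −0.32 (adjusted p = 1.2e-23, camera; adjusted p = 0.985 with an estimated correlation). Its leading members were DDR2, CTT1 and the trehalose synthesis gene TSL1 (2.88). Of 37 antioxidant genes, 24 rose, 0 fell and 13 did not pass (25 and 0 adjusted over the list alone), with a median shift of 0.86 (adjusted p = 2.2e-38, and adjusted p = 0.911 with an estimated correlation). Among 30 heat shock chaperone genes, 10 rose and 20 did not pass (11 rose adjusted over the list alone); HSP30, HSP31 (1.58) and HSP78 (1.22) led. The chaperone shift was 0.21 (adjusted p = 0.001, and adjusted p = 0.985 with an estimated correlation), but 0.032 against reference 1 and 0.39 against reference 2.

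The test pointed down for 6 lists, most of whose members did not pass. The median of 101 ribosome biogenesis genes shifted by −0.40 (adjusted p = 3.7e-12, and adjusted p = 0.985 with an estimated correlation), where 3 fell, RRP9 (−1.18), UTP9 (−1.16) and NOG2 (−1.12), and 98 did not pass (0 adjusted over the list alone). This shift was −0.69 against reference 1 and −0.15 against reference 2, and the references differed from each other by 0.55. RNA polymerase I and III subunits shifted by −0.33 (−0.60 against reference 1) with 0 of 17 called (0 adjusted over the list alone), the lowest being RPA12 (−0.70, adjusted p = 0.422). The list passed at adjusted p = 0.00631. Ergosterol synthesis genes shifted by −0.34 (adjusted p = 8.7e-05, and −0.19 against reference 1). CYB5 and HMG1 fell, as they did adjusted over the list alone, and 23 of 25 did not pass, with ERG1 at −1.07 (adjusted p = 0.0552). Cell cycle regulators shifted by −0.53 (adjusted p = 0.001), with FAR1 the 1 of 10 that fell and CDC5 at −0.77. Histone genes shifted by −0.30 (adjusted p = 0.0188), with 0 of 9 called and HTA1 at −0.78. The 127 cytosolic ribosomal protein genes, of which 0 were called over all genes or adjusted over the list alone, shifted by −0.067 (adjusted p = 0.0329). This shift turned to 0.022 after quantile normalization and was 0.23 before the median gene was taken off.

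The other 10 lists did not pass. Their shifts were 0.18 for mitochondrial ribosomal proteins (1 of 66 rose), 0.26 for proteasome subunits (1 of 33 rose, 0 adjusted over the list alone) and −0.034 for the pentose phosphate pathway (2 of 8 rose). The DNA damage response shifted by 0.12 (4 of 23 rose and 1 fell), sulfur and methionine metabolism by 0.023 (4 of 24 rose) and amino acid biosynthesis genes under Gcn4 by −0.017 (9 of 48 rose). The shift was −0.034 for glycolysis and fermentation (1 of 15 rose), 0.11 for oxidative phosphorylation (3 of 36 rose), −0.090 for translation factors (0 of 33) and 0.0023 for mRNA decay machinery (4 of 36 rose). Against reference 1 alone the shift was −0.10 for oxidative phosphorylation, 0.046 for Gcn4 genes, 0.16 for sulfur genes, −0.21 for translation factors and −0.0041 for mRNA decay. Quantile normalization turned the Gcn4 shift to 0.035, glycolysis to 0.064 and mRNA decay to −0.012. The median and the test differed in sign for the pentose phosphate, Gcn4 and mRNA decay lists, whose means were 0.25, 0.011 and −0.029. The chaperone, ribosome biogenesis, RNA polymerase I and III and ribosomal protein shifts were each smaller than the difference between the 2 references. On centred arrays with an estimated correlation, 3 lists passed: ribosome biogenesis, antioxidant defence and general stress (adjusted p = 0.0275 each).

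In all, 458 genes were higher and 30 lower under oxidative stress at time 0 (limma on 1 value per culture and gene). Centring each array on its median gave 118 higher and 30 lower, quantile normalization 81 and 7. Leaving out the first or the second time 0 array of each culture gave 153 and 0 or 137 and 3. ANB1, FAR1, PRM1 and TRX2 lost their calls when centred, and 141 genes were called both ways. With the scatter of arrays as the error, 1272 genes were called, 721 against reference 1 alone and 2220 against reference 2 alone, and 1100 higher and 1923 lower when centred as well, where reference 1 minus reference 2 gave 1187 and 1411.

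Under DNA damage SRX1, DDI3, FRM2 and MAG1 rose at time 0, and CYB5 and HTA1 fell. SRX1 rose 29.9-fold relative to the median gene (log2 4.90, standard error 0.29, 1 stressed against 2 reference cultures, adjusted p = 8.4e-38) and FRM2 18.9-fold. DDI3 (YFL061W), a gene known to respond to methyl methanesulfonate whose probe set is shared with a near-identical copy, rose 20.9-fold (log2 4.39, adjusted p = 4.1e-32), and MAG1 (YER142C), the 3-methyladenine DNA glycosylase that removes alkylated bases, 2.65-fold (adjusted p = 7.8e-04). CYB5, the cytochrome b5 gene, fell by 2.27 (adjusted p = 7.2e-13) and HTA1, a histone H2A gene, fell by 1.72 (adjusted p = 6.4e-08).

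Further large rises were OYE3 (3.67), AAD4 (3.39, shared probe set), TSA2 (3.18), GTT2 (3.09), ECM4 (3.05), the drug transporter gene FLR1 (3.02) and YIL165C (2.94). Further falls were NDE1 (−1.59), a mitochondrial NADH dehydrogenase gene, HPT1 (−1.58), the ribosome assembly GTPase genes NOG1 (−1.55) and NOG2 (−1.36), the squalene epoxidase gene ERG1 (−1.50), YBL100W-A (−1.45, shared probe set), PXR1 (−1.36) and RIP1 (−1.34). Against reference 2 alone SRX1 stood at 4.68, DDI3 at 4.18, HTA1 at −1.63 and YBL100W-A at −0.77. SRX1, FRM2, DDI3, OYE3 and TSA2 were among the 9 of 111 higher genes below the filter of 11.04 in both references, so their folds are not exact, nor is the fall of YBL100W-A to 10.21. CTT1 stood at 0.12 (adjusted p = 0.964), TRX2 at 0.030 (adjusted p = 0.878), HSP12 at −0.65 (adjusted p = 0.0822), RPL3 at −0.35 (adjusted p = 0.345) and NOP56 at −0.32 (adjusted p = 0.379). The damage genes RNR3 and HUG1 averaged 11.03 and 11.01 over all arrays, below the filter of 11.04, and were not tested. At time 0 RNR3 stood at 10.79, 11.13, 11.45 and 11.76 and HUG1 at 10.66, 11.55, 10.80 and 11.69 in reference 1, reference 2, oxidative stress and DNA damage.

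The lists that rose were antioxidant defence, general stress and the DNA damage response. Of 37 antioxidant genes 11 rose and 26 did not pass (13 rose adjusted over the list alone), with a median shift of 0.39 (adjusted p = 1.5e-18, and adjusted p = 0.859 with an estimated correlation). Of 41 general stress genes 6 rose, 1 fell and 34 did not pass (8 and 2 adjusted over the list alone). DDR2 (2.16), TSL1 (1.60) and GPD1 (1.54) led, and the shift of 0.47 passed (0.29 against reference 2; adjusted p = 3.9e-06, and adjusted p = 0.859 with an estimated correlation). Of 23 DNA damage response genes 3 rose, DDI3, MAG1 and DDI1 (1.36), and 20 did not pass (3 rose and 1 fell adjusted over the list alone), with a shift of 0.36 (adjusted p = 2.4e-04, and adjusted p = 0.859 with an estimated correlation).

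Histone genes showed the largest list shift, −0.99 (−1.07 against reference 1 and −0.92 against reference 2). Of 9 members 7 fell, over all genes and adjusted over the list alone, among them HTA1, HTB2 (−1.27) and HTA2 (−1.23, shared probe set), and 2 did not pass (adjusted p = 6.6e-08, and adjusted p = 0.859 with an estimated correlation). Ribosome biogenesis genes shifted by −0.56 (adjusted p = 1.5e-18, and adjusted p = 0.859 with an estimated correlation), where 30 of 101 fell and 71 did not pass (59 fell adjusted over the list alone), led by NOG1, NOG2 and RRS1 (−1.24). RNA polymerase I and III subunits shifted by −0.54 (adjusted p = 3.8e-06, and adjusted p = 0.859 with an estimated correlation). Of these, 4 of 17 fell (11 adjusted over the list alone), with RPA12 (−1.13), RPC19 (−1.12) and RPA135 (−0.81) leading. Both shifts were smaller against reference 2, −0.27 and −0.24, and the references differed by 0.55 and 0.56 on these lists. Oxidative phosphorylation genes shifted by −0.51 (adjusted p = 1.2e-08, and adjusted p = 0.859 with an estimated correlation), where 8 of 36 fell (18 adjusted over the list alone), among them NDE1, RIP1 and CYT1 (−0.97); the references differed by 0.32. Ergosterol synthesis genes shifted by −0.45 (adjusted p = 8.8e-08, and adjusted p = 0.859 with an estimated correlation). Of these, 4 of 25 fell (11 adjusted over the list alone), with CYB5, ERG1 and HMG1 (−1.17) leading, and the shift was −0.19 after quantile normalization.

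The lists of translation factors, ribosomal proteins and glycolysis passed with shifts below 0, while most of their members did not pass. Translation factors shifted by −0.39 (−0.14 after quantile normalization; adjusted p = 5.5e-05, and adjusted p = 0.859 with an estimated correlation), where TIF3 (−0.91) and NIP1 (−0.86) fell and 31 of 33 did not pass (6 fell adjusted over the list alone). Cytosolic ribosomal protein genes shifted by −0.38 (adjusted p = 9.1e-11, and adjusted p = 0.859 with an estimated correlation), which turned to 0.019 after quantile normalization. Of 127 members 4 fell over all genes and adjusted over the list alone, RPS28B (2.30-fold lower), RPS10B (−0.91, shared probe set) and RPL36A (−0.79) the furthest, and 123 did not pass. Glycolysis and fermentation genes shifted by −0.35 with 0 of 15 called over all genes or adjusted over the list alone (adjusted p = 0.0143, and adjusted p = 0.892 with an estimated correlation), ENO1 (−0.54) and TDH3 (−0.41) the lowest, and this shift turned to 0.057 after quantile normalization.

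The other 8 lists did not pass. Shifts were 0.095 for mitochondrial ribosomal proteins and 0.092 for proteasome subunits, with 0 members called. The pentose phosphate pathway shifted by −0.35 (0 of 8, 1 rose adjusted over the list alone) and heat shock chaperones by −0.13 (2 rose and 1 fell of 30). The shift was −0.020 for sulfur and methionine metabolism (4 rose and 1 fell of 24), −0.0035 for Gcn4 genes (2 of 48 rose), −0.054 for cell cycle regulators (1 of 10 fell) and 0.052 for mRNA decay machinery (0 of 36). Against reference 2 alone chaperones shifted by 0.060, sulfur genes by −0.17, Gcn4 genes by −0.019 and cell cycle regulators by −0.16. After quantile normalization the Gcn4 shift was 0.30, the proteasome shift 0.33, chaperones 0.029, the pentose phosphate pathway −0.076, cell cycle regulators −0.18, sulfur genes −0.055 and mitochondrial ribosomal proteins 0.051. The means of the sulfur and Gcn4 lists, 0.040 and 0.11, lay on the other side of 0 from their medians, as did their tests. On centred arrays with an estimated correlation, ribosome biogenesis passed (adjusted p = 0.0455), as 1 list did between the references.

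In all, 111 genes were higher and 123 lower under DNA damage at time 0. Centring gave 52 and 19, quantile normalization 26 and 1. Leaving out the first or second time 0 array gave 32 and 6 or 26 and 3. Both as deposited and centred, 71 genes were called, while NDE1, MAG1, TSL1, GPD1, CYT1, TIF3, NIP1, RRS1, RPA12, RPC19, RPA135, PXR1, YBL100W-A, RPS10B and RPL36A were not. With the scatter of arrays as the error, 301 genes were higher and 762 lower, 879 in all were called against reference 2 alone and 1048 against reference 1 alone, and 1206 were higher and 1956 lower when centred as well, against 2598 in all between the references.

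Genes called in both stresses overlapped: 100 were higher in both, where independent lists of these sizes would share 13.0, and 13 were lower in both (0.946). Both comparisons use the same reference cultures, and part of the overlap may come from them. Across genes, which are not independent replicates, the level differences of the stresses correlated at r = 0.689, against 0.334 in 100 simulations without effects. The covariance was 0.189 against a simulated 0.0276, a difference of 0.161. With each stress set against the reference of its own spike-in pattern the correlation was 0.723, and with the references exchanged 0.386.

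In the direct comparison at time 0, CTT1 and CTA1 were higher under oxidative stress, and DDI3 and SSU1 under DNA damage. Relative to the median gene, CTT1 was 7.58-fold higher under oxidative stress than under DNA damage (log2 2.92, standard error 0.33, 1 culture each, adjusted p = 1.9e-17) and the peroxisomal catalase gene CTA1 7.29-fold (2.87). DDI3 was 25.0-fold lower (−4.64, adjusted p = 2.2e-24), and the sulfite exporter gene SSU1 was also lower (−2.89, adjusted p = 2.4e-09). Within spike-in patterns these differences were 2.84, 3.09, −4.23 and −3.09. DDI3 lay at 10.68 under oxidative stress, and CTT1 and CTA1 at 10.99 and 10.72 under DNA damage, below the filter of 11.04, so these folds are not exact. RNR1 stood at −1.86, and at −1.62 within patterns.

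Other genes higher under oxidative stress were YRO2 (2.44, and 0.84 within patterns), FMP48 (2.18 and 0.83), YBL100W-A (2.08 and 0.72), HPF1 (2.08 and 0.037), YER053C-A (2.05 and 1.18), DDR2 (2.04 and 2.83), HSP12 (1.96 and 1.62), HSP30 (1.90 and 0.73) and TSA2 (1.87 and 2.05). Genes higher under DNA damage were ADH5 (−2.93, and −0.23 within patterns), TIR1 (−2.78 and 0.28), IMD2 (−2.60 and −0.16, shared probe set), ANB1 (−2.59 and −0.35), FIT2 (−2.49 and −1.58), FAR1 (−1.87 and −0.79) and FUS1 (−1.84 and −0.73). ADH5, TIR1, IMD2, ANB1 and HPF1 thus differed little, or the other way, once each stress was set against its own reference. FMP48 (10.07), YBL100W-A (10.21) and HPF1 (10.69) lay below the filter under DNA damage and IMD2 (10.56) under oxidative stress, so their differences are not exact either. TRX2 (0.46, adjusted p = 0.0535), MAG1 (−0.039, adjusted p = 0.318), RPO21 (0.073, adjusted p = 0.219), RPL3 (0.30, adjusted p = 0.102) and NOP56 (0.21, adjusted p = 0.136) did not pass.

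Of the lists, 9 were higher under oxidative stress than under DNA damage at time 0. Histone genes shifted by 0.69 (0.44 within patterns; adjusted p = 0.00184, and adjusted p = 0.946 with an estimated correlation) with 6 of 9 higher, HTA2, HTA1 and HHF1 leading (0.96, 0.89 and 0.83). Oxidative phosphorylation shifted by 0.55 (0.31 within patterns; adjusted p = 2.1e-13, and adjusted p = 0.946 with an estimated correlation), with 22 of 36 higher (33 adjusted over the list alone), among them NDE1 (1.67) and CYC1 (1.52). Antioxidant genes shifted by 0.41 (0.42 within patterns, and 0.22 after quantile normalization; adjusted p = 7.9e-12, and adjusted p = 0.946 with an estimated correlation), with 14 of 37 higher (28 adjusted over the list alone). General stress genes shifted by 0.39 (0.81 within patterns; adjusted p = 2.1e-13, and adjusted p = 0.946 with an estimated correlation), with 19 of 41 higher and 1 lower (29 and 1 adjusted over the list alone). Pentose phosphate genes shifted by 0.32 (0.27 within patterns, and 0.14 after quantile normalization; adjusted p = 0.0111, and adjusted p = 0.946 with an estimated correlation). SOL4 (1.40, at 10.70 under DNA damage) and ZWF1 (0.80), the gene of glucose 6-phosphate dehydrogenase, were the 2 of 8 higher (5 adjusted over the list alone).

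Chaperones shifted by 0.31 with 8 of 30 higher (21 adjusted over the list alone), HSP26 (1.29, at 10.93 under DNA damage) and BTN2 (2.29-fold) among them (adjusted p = 4.5e-06, and adjusted p = 0.946 with an estimated correlation), but within patterns the chaperone shift was −0.0060 and BTN2 stood at −1.29. Glycolysis shifted by 0.27 (0.27 within patterns; adjusted p = 0.0226, and adjusted p = 0.946 with an estimated correlation), with TDH1 (1.01) and ENO1 (0.53) the 2 of 15 higher (12 adjusted over the list alone). Cytosolic ribosomal proteins shifted by 0.26 (0.18 within patterns; adjusted p = 6.0e-06, and adjusted p = 0.946 with an estimated correlation), with 7 of 127 higher (105 adjusted over the list alone). After quantile normalization the glycolysis shift was 0.0035 and the ribosomal protein shift −0.0074. Translation factors shifted by 0.23 (0.028 within patterns, and 0.062 after quantile normalization; adjusted p = 0.0226, and adjusted p = 0.946 with an estimated correlation), with 4 of 33 higher (13 adjusted over the list alone), TIF3 (0.59) leading. Cell cycle regulators shifted by −0.42 (−0.36 within patterns, and 0.064 before the median gene was taken off; adjusted p = 1.6e-04, and adjusted p = 0.946 with an estimated correlation), FAR1 being the 1 of 10 lower. The DNA damage response had a median shift of −0.039 (−0.068 after quantile normalization, and 0.45 before the median gene was taken off) and a mean of −0.36 (adjusted p = 8.8e-04, and adjusted p = 0.946 with an estimated correlation), with DDI3 and RNR1 the 2 of 23 lower.

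Of the lists that did not pass, ribosome biogenesis shifted by 0.089 (13 of 101 higher) but by −0.49 within patterns, RNA polymerase I and III by 0.19 but −0.33, and Gcn4 genes by −0.057 but 0.078. The others were mitochondrial ribosomal proteins (0.058, and 0.15 within patterns), the proteasome (0.11 and 0.042), sulfur metabolism (0.010 and 0.30, with a mean of −0.0080 and the test on that side), ergosterol synthesis (0.14 and 0.17) and mRNA decay (−0.026 and −0.12). Quantile normalization turned the proteasome shift to −0.086, ergosterol synthesis to −0.048 and mRNA decay to 0.040, and gave −0.28 for Gcn4 genes, 0.12 for mitochondrial ribosomal proteins and 0.067 for sulfur genes. In all, 311 genes were higher and 13 lower under oxidative stress than under DNA damage. Centring left 2 higher, CTT1 and CTA1, and 2 lower, DDI3 and SSU1, and quantile normalization 0 and 1. Without the first time 0 arrays 31 were higher and 4 lower, without the second 2 and 1. With the scatter of arrays as the error 1927 were higher and 46 lower, 2615 or 1590 in all without reference 1 or reference 2, and 1690 higher and 1239 lower when centred as well, against 2598 in all between the references. Of the 324 genes called, 233 differed the same way between reference 1 and reference 2.

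In the reference cultures, 37 of 41 general stress genes had a higher slope than the median gene after the shift, and 88 of 101 ribosome biogenesis genes a lower one. Relative to the median gene, the slope of the small heat shock gene HSP26 was 1.25 log2 per 10 min higher (standard error 0.056, 2 reference cultures, adjusted p = 0.00437), with slopes of 0.77 and 1.03 in the references, so its value rose with time. TFS1 (1.13), HSP12 (1.13), CTT1 (1.12) and the Hsp70 gene SSA4 (1.08) followed. NOP13 lay lowest at −1.15 (standard error 0.14, adjusted p = 0.0105), followed by DRS1 and RPF2 (−1.12), ENP2 (−1.10) and NOP7 (−1.09), all genes of ribosome assembly. Slower and faster stand below for a higher and a lower slope than that of the median gene, rising genes included.

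Other slow genes were SOL4 (1.06), SSA3 (1.05), GAD1 (1.03), GPH1 (1.01) and SPI1 (0.98), and other fast genes were NIP7 (−1.07), PXR1 (−1.07), NSR1 (−1.06), DBP3 (−1.06), NMD3 (−1.04) and NOP56 (−0.64). SOL4 and TSA2 (0.18, adjusted p = 0.0455) lay below the filter of 11.04 at time 0 in both references, so their decay there was not measured. RPL3 (−0.0022, adjusted p = 0.979), RPO21 (−0.051, adjusted p = 0.412), TRX2 (0.070, adjusted p = 0.239) and MAG1 (0.16, adjusted p = 0.0588) did not pass. In all 4 cultures, 80 genes had a positive slope.

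Of 41 general stress genes, 37 were slower than the median gene and 4 did not pass (39 adjusted over the list alone), with a shift of 0.49 (adjusted p = 1.8e-19, and adjusted p = 0.624 with an estimated correlation on centred arrays). Chaperones shifted by 0.20 with 16 of 30 slower and 1 faster, the same adjusted over the list alone (adjusted p = 1.0e-05, and adjusted p = 0.771 with an estimated correlation). Sulfur genes shifted by 0.16, 9 of 24 slower and 1 faster (10 and 2 adjusted over the list alone), MUP1 and MET1 leading at 0.54 (adjusted p = 0.0192, and adjusted p = 0.775 with an estimated correlation). Antioxidant genes shifted by 0.14, 17 of 37 slower and 2 faster, the same adjusted over the list alone, with PRX1 at 0.51, and CTA1, below the filter in both references, at 0.38 (adjusted p = 0.00114, and adjusted p = 0.624 with an estimated correlation). Proteasome genes shifted by 0.053, with RPN2 and PUP1 (0.17) the 2 of 33 slower (0 adjusted over the list alone; list adjusted p = 0.0456, and adjusted p = 0.465 with an estimated correlation).

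Ribosome biogenesis genes shifted by −0.70, with 88 of 101 faster and 13 not passing (92 adjusted over the list alone; list adjusted p = 1.0e-24, and adjusted p = 0.465 with an estimated correlation). RNA polymerase I and III subunits shifted by −0.51, 13 of 17 faster (16 adjusted over the list alone), RPA135 at −0.97 (adjusted p = 1.8e-07, and adjusted p = 0.465 with an estimated correlation). Histone genes shifted by −0.22, 5 of 9 faster (9 adjusted over the list alone), HTB2 at −0.45 (adjusted p = 6.5e-04, and adjusted p = 0.465 with an estimated correlation). Translation factors shifted by −0.17, 15 of 33 faster and 1 slower (19 and 1 adjusted over the list alone), TIF4631 at −0.64 (adjusted p = 3.4e-05, and adjusted p = 0.465 with an estimated correlation). Gcn4 genes shifted by −0.079, 17 of 48 faster (19 faster and 1 slower adjusted over the list alone), ILV5 at −0.49 and LYS4 at −0.47 (adjusted p = 0.00503, and adjusted p = 0.624 with an estimated correlation).

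Lists that did not pass were cytosolic ribosomal proteins (−0.012, 12 of 127 faster, 0 adjusted over the list alone), mitochondrial ribosomal proteins (−0.028), the pentose phosphate pathway (0.042), the DNA damage response (0.052), glycolysis (0.010), oxidative phosphorylation (0.020), ergosterol synthesis (−0.0065), cell cycle regulators (−0.039) and mRNA decay (−0.035). The glycolysis test pointed down against a positive median and mean, and the ergosterol and cell cycle means (0.0099 and 0.0095) lay on the other side of 0 from the median and the test. In all, 556 genes were slower and 677 faster than the median gene (limma). The count was 367 and 427 without the 5 min arrays, 973 and 1101 without those at 30 min, and 0 and 0 from 5 to 30 min alone, where 1215 genes had an unadjusted p under 0.05. With the scatter of arrays as the error 1433 genes were called in all, and 527 from reference 2 alone.

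Under oxidative stress, SRX1, ATR1, CTA1, OYE3, DDR2 and CTT1 had lower slopes after the shift than in the references. The slope of SRX1 was lower by −1.12 log2 per 10 min (standard error 0.16, 1 stressed against 2 reference cultures, adjusted p = 2.4e-09), at −1.59 against −0.45 and −0.47 in the references. ATR1 (−0.93, adjusted p = 5.5e-06), a multidrug transporter gene, CTA1 (−0.86), OYE3 (−0.81), DDR2 (−0.81) and CTT1 (−0.62, adjusted p = 0.0159) followed. SRX1, CTA1, OYE3 and AAD6 lay below the filter of 11.04 in both references at time 0, so their decay in the references was not measured; the slope of probe sets at the array floor was −0.43 and −0.33 there. Of the 30 genes with a lower slope, 22 lay above the filter in every culture compared, ATR1 and the glutathione synthesis gene GSH1 (−0.61, named after its values were seen) among them. CTT1 and DDR2 rose with time in the references, at 0.79 and 0.75 for CTT1, where the slope under oxidative stress was 0.15. HXT1, a glucose transporter gene, was the 1 gene with a higher slope (0.55, adjusted p = 0.0481).

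FMP23 (−0.82), RPM2 (−0.80), YIL165C (−0.75), the sulfate assimilation gene MET16 (−0.71) and YGL114W (−0.69) were the other genes with the largest falls. FMP23 (10.63) and DDR2 (11.03) in reference 1 and CTT1 (10.90) in reference 2 lay below the filter at time 0, so their decay was not measured there. Against reference 1 alone SRX1 differed by −1.13, ATR1 by −0.89 and MET16 by −0.49. TSA2 (−0.019), MAG1 (−0.20), NOP56 (−0.19), RPL3 (0.0066), TRX2 (0.00085) and RPO21 (0.073) had an adjusted p of 0.999, and HSP12 stood at −0.36 (adjusted p = 0.806). References and stress started from different levels, and SRX1 fell from 16.62 in the stressed culture against 10.66 and 10.94 in the references.

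Antioxidant genes shifted by −0.10 log2 per 10 min relative to the median gene, 6 of 37 with a lower slope and 31 not passing (7 adjusted over the list alone; list adjusted p = 4.2e-13, and adjusted p = 0.990 with an estimated correlation). Of these 6, ATR1 and GSH1 lay above the filter at time 0 in every culture compared. General stress genes shifted by −0.16, where CTT1 and DDR2 had a lower slope than in the references and 39 of 41 did not pass (2 adjusted over the list alone; list adjusted p = 4.6e-09, and adjusted p = 0.990 with an estimated correlation); the references differed by 0.12. Sulfur and methionine genes shifted by −0.14, MET16 being the 1 of 24 that fell faster and MUP1 at −0.44 (adjusted p = 6.1e-08, and adjusted p = 0.990 with an estimated correlation), but by −0.056 against reference 1 and −0.23 against reference 2. Gcn4 genes shifted by −0.10 with 0 of 48 called over all genes or adjusted over the list alone, ARG4 lowest at −0.46 (adjusted p = 0.275; list adjusted p = 2.1e-06, and adjusted p = 0.990 with an estimated correlation). Cytosolic ribosomal proteins shifted by −0.047 with 0 of 127 called over all genes or adjusted over the list alone (list adjusted p = 0.00299, and adjusted p = 0.990 with an estimated correlation), which was 0.011 before the median gene was taken off.

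The other 14 lists did not pass. Among them were mitochondrial ribosomal proteins (−0.021), ribosome biogenesis (−0.039; 0.16 against reference 1 and −0.26 against reference 2), RNA polymerase I and III (−0.046; 0.068 against reference 1), the proteasome (−0.058), the pentose phosphate pathway (0.046), chaperones (−0.019) and the DNA damage response (0.023). The others were glycolysis (−0.018; 0.0016 against reference 1), oxidative phosphorylation (0.044), translation factors (−0.026), ergosterol synthesis (0.0022; −0.0034 against reference 1), histones (0.0042; 0.070 against reference 1), cell cycle regulators (0.11) and mRNA decay (0.022). Quantile normalization turned ribosome biogenesis to 0.0054, chaperones to 0.0034 and histones to −0.0014. The means of the pentose phosphate and glycolysis lists, −0.044 and 0.016, and their tests lay opposite to the medians. In all, 1 gene was higher and 30 lower in slope (limma). Without the 5 min arrays the counts were 0 and 5, without 20 min 0 and 17, without 30 min 39 and 105, and without reference 1, by the scatter of arrays, 17 in all against 46 with both references. Centring and quantile normalization each gave 0, with 286 and 345 genes at an unadjusted p under 0.05 (limma), while a fit on centred arrays with their scatter as the error called 425, of which 28 were among the 31, and 56 between the references.

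Under DNA damage, 22 of 127 cytosolic ribosomal protein genes fell faster after the shift. RPS16B (−0.86 log2 per 10 min, standard error 0.16, 1 stressed against 2 reference cultures, adjusted p = 4.9e-05), RPL16A (−0.85), RPS0B (−0.85), RPL13A (−0.84) and RPL27B (−0.82), genes of both ribosomal subunits, were among the 10 largest falls. RPL16A had a slope of −1.43 under DNA damage, −0.63 and −0.52 in the references and −0.80 under oxidative stress. SCM4 fell fastest relative to the references (−0.90, adjusted p = 2.9e-05). RPF1 (0.83, adjusted p = 7.0e-05) and ENP2 (0.72), genes of ribosome assembly, fell more slowly.

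CYB5 (−0.81), SNU13 (−0.80), the ribosome-associated Hsp70 gene SSB2 (−0.79) and RPL22B (−0.78) completed the largest falls, and MPD1 (0.64), ADE17 (0.63), RMT2 (0.62), LTV1 (0.60), DBP9 (0.59), NOB1 (0.58), YBL086C (0.58) and YNL195C (0.58) the largest differences upward. YNL195C lay below the filter at time 0 in reference 2 and under DNA damage (10.80 and 10.65). Against reference 2 alone RPS16B differed by −0.94, RPL16A by −0.90, RPF1 by 0.57 and ADE17 by 0.16. TSA2 stood at 0.41 (adjusted p = 0.208), HSP12 at 0.19 (adjusted p = 0.803), MAG1 at 0.13 (adjusted p = 0.916), NOP56 at 0.13 (adjusted p = 0.908), RPO21 at −0.11 (adjusted p = 0.928), and CTT1 (0.059), TRX2 (0.063) and RPL3 (0.064) at an adjusted p of 0.973.

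**Figure D2:**
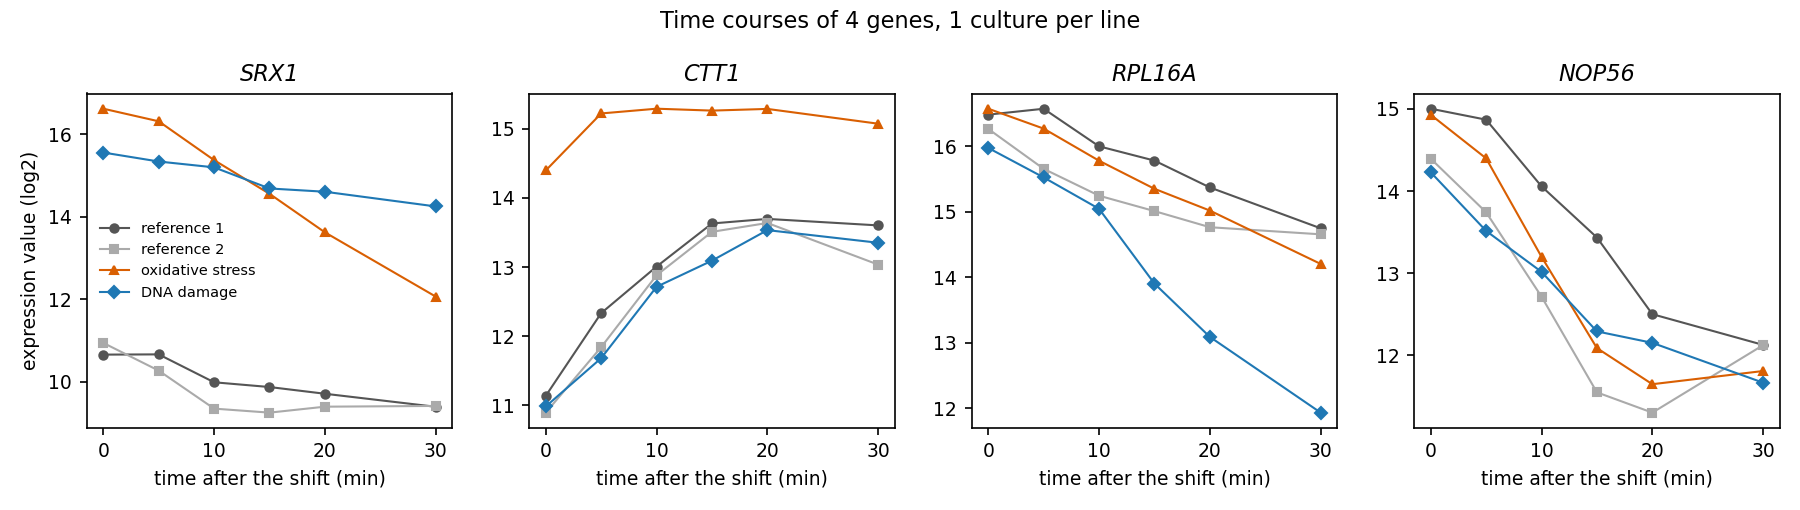
Log2 expression value against time after the temperature shift (0 to 30 min) for SRX1, CTT1, RPL16A and NOP56, 1 culture per line, time 0 being the mean of 2 arrays. SRX1 had a slope of −1.59 log2 per 10 min under oxidative stress, and RPL16A of −1.43 under DNA damage.

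Of 127 cytosolic ribosomal protein genes 22 fell faster, 0 fell more slowly and 105 did not pass (40 and 0 adjusted over the list alone). The median shift was −0.31 (−0.29 against reference 1 and −0.32 against reference 2; adjusted p = 5.3e-38, and adjusted p = 0.964 with an estimated correlation). RPL3 was not among them. Ergosterol synthesis genes shifted by −0.19, 4 of 25 falling faster (5 adjusted over the list alone), CYB5, ERG5 (−0.70) and HMG1 (−0.66) leading (adjusted p = 2.9e-08, and adjusted p = 0.964 with an estimated correlation). Oxidative phosphorylation shifted by −0.17, with COX7 (−0.58) and CYC1 (−0.52) the 2 of 36 that fell faster, also adjusted over the list alone (adjusted p = 3.6e-05, and adjusted p = 0.964 with an estimated correlation). Cell cycle regulators shifted by −0.19 (−0.052 after quantile normalization) with 0 of 10 called and FAR1 at −0.43 (adjusted p = 0.163; list adjusted p = 0.0205, and adjusted p = 0.964 with an estimated correlation). Sulfur genes shifted by −0.15 (−0.30 against reference 2), SAH1 (−0.54) being the 1 of 24 that fell faster (4 adjusted over the list alone; list adjusted p = 7.5e-04, and adjusted p = 0.964 with an estimated correlation). Proteasome genes shifted by 0.11 with 0 of 33 called, RPT2 at 0.23 (list adjusted p = 0.00158, and adjusted p = 0.964 with an estimated correlation). DNA damage response genes shifted by 0.094 with 0 of 23 called, RAD16 at 0.41 (list adjusted p = 0.0296, and adjusted p = 0.964 with an estimated correlation). On centred arrays with an estimated correlation, ergosterol synthesis passed (adjusted p = 0.0124).

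The other 12 lists did not pass. Among them were mitochondrial ribosomal proteins (0.041), ribosome biogenesis (−0.024, and −0.20 against reference 2; 7 slower and 4 faster of 101), RNA polymerase I and III (−0.095, and −0.19 against reference 2), antioxidant defence (0.018), the pentose phosphate pathway (−0.17), general stress (0.028, and 0.083 against reference 2) and chaperones (0.011). The others were Gcn4 genes (−0.0078), glycolysis (0.0068, and −0.024 against reference 2), translation factors (−0.089), histones (0.077, and 0.028 against reference 2) and mRNA decay (0.0071, and −0.019 against reference 2). Quantile normalization turned ribosome biogenesis to 0.037, glycolysis to −0.031 and mRNA decay to −0.0078, and gave 0.088 for general stress. The means of ribosome biogenesis and glycolysis, 0.011 and −0.020, and their tests lay opposite to the medians. In all, 16 genes were higher and 55 lower in slope (limma). Without the 5 min arrays the counts were 2 and 45, and without those at 30 min 518 and 105. By the scatter of arrays 113 were higher and 93 lower, and 102 or 237 in all without reference 1 or reference 2. Centring and quantile normalization gave 0, with 743 and 851 genes at an unadjusted p under 0.05 (limma), while a fit on centred arrays with their scatter as the error called 1452, 61 of them among the 71.

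Slope differences of the stresses shared 1 gene lower in both, where independent lists would share 0.423, and 0 higher (0.0041; 158 and 407 genes had an unadjusted p under 0.05 by limma). Across genes these differences correlated at r = 0.132 against 0.332 in simulations without effects, and the covariance differed from the simulated one by −0.0045. With separate references the correlation was −0.041 or −0.051.

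**Figure D3:**
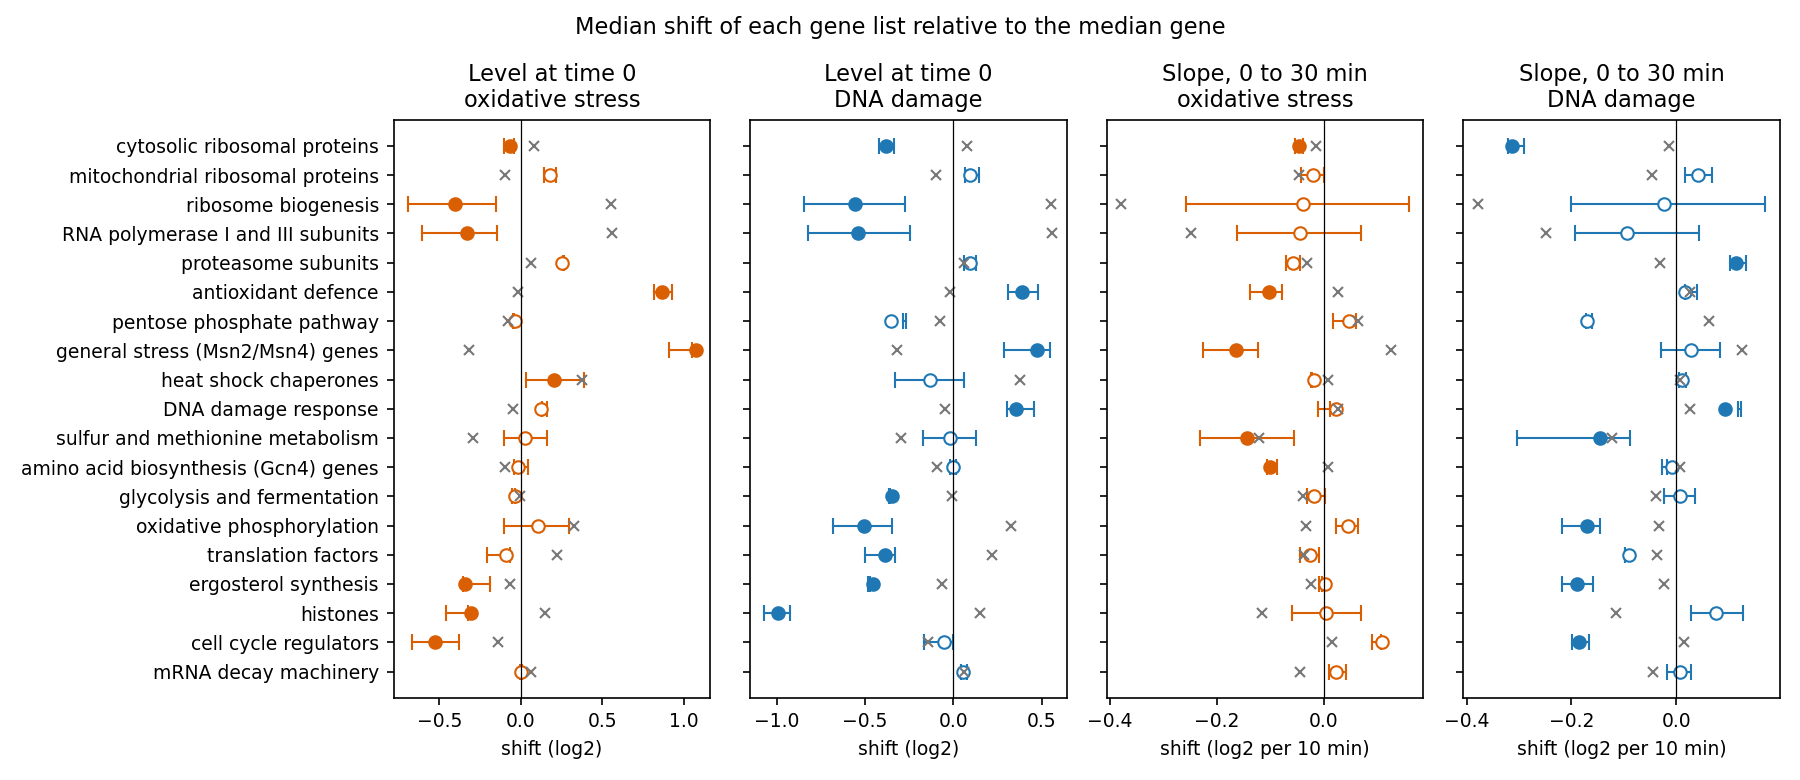
Median shift of each gene list relative to the median gene, in log2 (level at time 0, left pair of panels) and log2 per 10 min (slope over 0 to 30 min, right pair); circles are the main values, filled where the list passed its test, bars end at the values against reference 1 and reference 2, and crosses are reference 1 minus reference 2. Histones under DNA damage (−0.99) and general stress genes under oxidative stress (1.07) lie furthest from 0 in level, and ribosomal proteins under DNA damage (−0.31) in slope, and after quantile normalization the level shift of ribosomal proteins was 0.019 under DNA damage and 0.022 under oxidative stress.

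In the direct comparison of slopes, CYB5, GLN1, FCY2 and HMG1 were lower under DNA damage, and SRX1, FMP23 and ATR1 under oxidative stress. CYB5 differed by 1.10 log2 per 10 min (standard error 0.18, 1 culture each, adjusted p = 1.4e-06; 1.53 within spike-in patterns), GLN1, the glutamine synthetase gene, by 1.03 (1.22), FCY2 by 1.00 (1.41) and HMG1, of sterol synthesis, by 0.98 (1.22). SRX1 differed by −1.13 (adjusted p = 1.2e-06; −1.15 within patterns), FMP23 by −1.11 (−1.06) and ATR1 by −0.95 (−0.87). ADE17 differed by −0.85 but by 0.084 within patterns, and RPF1 by −0.97 and −0.45.

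Other differences upward were ATF2 (0.90), ERG5 (0.89), PDR12 (0.89), SCM4 (0.84), SSB2 (0.82) and UTP15 (0.79), and downward TCB2 (−0.90), CTA1 (−0.88), AAD6 (−0.85), OYE3 (−0.82), ISU2 (−0.81) and CTT1 (−0.68). At time 0 CTA1 and CTT1 lay below the filter under DNA damage. TSA2 (−0.43, adjusted p = 0.293), HSP12 (−0.54, adjusted p = 0.0884), MAG1 (−0.32, adjusted p = 0.562), NOP56 (−0.32, adjusted p = 0.563), RPO21 (0.18, adjusted p = 0.865), TRX2 (−0.062) and RPL3 (−0.057), the last 2 at an adjusted p of 0.991, did not pass.

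Ribosomal proteins shifted by 0.25 (0.26 within patterns; adjusted p = 3.5e-18, and adjusted p = 0.913 with an estimated correlation) with 14 of 127 higher (28 adjusted over the list alone), RPS19A (0.76) leading. Oxidative phosphorylation shifted by 0.20 (0.24 within patterns; adjusted p = 3.8e-07, and adjusted p = 0.913 with an estimated correlation), COX7 (0.63) being the 1 of 36 higher. Ergosterol synthesis shifted by 0.16 (0.19 within patterns; adjusted p = 5.0e-08, and adjusted p = 0.913 with an estimated correlation) with 5 of 25 higher (7 adjusted over the list alone). Cell cycle regulators shifted by 0.29 (0.25 within patterns; adjusted p = 3.0e-04, and adjusted p = 0.913 with an estimated correlation), FAR1 (0.63) being the 1 of 10 higher (2 adjusted over the list alone). General stress genes shifted by −0.18 (−0.36 within patterns; adjusted p = 6.7e-07, and adjusted p = 0.913 with an estimated correlation), with CTT1 the 1 of 41 lower (3 adjusted over the list alone). The proteasome shifted by −0.17 (−0.15 within patterns; adjusted p = 1.2e-04, and adjusted p = 0.913 with an estimated correlation) with 0 of 33 called. Antioxidant genes shifted by −0.16 (−0.15 within patterns; adjusted p = 5.0e-08, and adjusted p = 0.913 with an estimated correlation) with 5 of 37 lower (6 adjusted over the list alone). Gcn4 genes shifted by −0.076 (−0.069 within patterns; adjusted p = 0.0492, and adjusted p = 0.999 with an estimated correlation), with ARG1 (−0.67), HIS1 (−0.62) and ARG3 (−0.60) the 3 of 48 lower, also adjusted over the list alone. On centred arrays with an estimated correlation, ergosterol synthesis and the proteasome passed (adjusted p = 0.0272 each).

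Of the lists that did not pass, ribosome biogenesis shifted by −0.046 but by 0.35 within patterns, sulfur metabolism by −0.031 but 0.13, histones by −0.040 but 0.051, and glycolysis by −0.023 but 0.029 (its mean was 0.036, with the test on that side). The others were RNA polymerase I and III (0.028, and 0.26 within patterns), mitochondrial ribosomal proteins (−0.066 and −0.0093), the pentose phosphate pathway (0.18 and 0.16), chaperones (−0.041 and −0.059), the DNA damage response (−0.15 and −0.13), translation factors (0.074 and 0.094) and mRNA decay (0.0099 and 0.053). Quantile normalization turned the glycolysis shift to 0.017, and gave −0.093 for the DNA damage response. In all, 51 genes had a higher and 31 a lower slope under oxidative stress than under DNA damage (limma). Without the 20 min arrays the counts were 34 and 14, and without those at 30 min 82 and 381. By the scatter of arrays 182 genes were called, and 161 or 295 without reference 1 or reference 2. Centring and quantile normalization gave 0, with 780 and 821 genes at an unadjusted p under 0.05 (limma), while a fit on centred arrays with their scatter as the error called 1417, 75 of them among the 82.

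Whether genes whose level had changed at time 0 also changed in slope was described across genes, which are not independent replicates, with the level from time 0 arrays and the slope from 5 to 30 min. The correlations take a different reference culture for level and slope, while the counts and medians of called genes share the references between both. Of 458 genes higher under oxidative stress, SRX1, OYE3, DDR2 and CTT1 among them, 362 (79.0%) had a lower slope. Their median slope difference was −0.12 relative to the median gene (−0.17 against reference 1 and −0.088 against reference 2). Of the 30 lower genes 10 (33.3%) did, with a median of 0.081 (0.16 and 0.037). Over all genes r was −0.376 (−0.153 and −0.60 in the 2 arrangements of the references) and Spearman's rho −0.258 (−0.027 and −0.490). Under DNA damage r was 0.215 (0.336 and 0.094) and rho 0.276 (0.372 and 0.181). Of 111 higher genes 60 (54.1%) had a lower slope, with a median difference of −0.092 against reference 1 and 0.025 against reference 2. Of 123 lower genes, HTA1, NOG1 and CYB5 among them, 85 (69.1%) did, but their median difference was 0.0051 against reference 1 and −0.27 against reference 2. The difference between the stresses was not tested. Reference 1 minus reference 2 gave r = −0.317.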

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

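Tests of the general stress rise and of the relation between level and slope, and the test of culture spread for ribosomal proteins, were chosen only after the result was seen.

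The 2 stressed cultures, 1 for each stress, differed in 11 lists at time 0 by the test of the difference itself. These were histones (0.69, oxidative stress minus DNA damage), oxidative phosphorylation (0.55), antioxidant defence (0.41), general stress (0.39), the pentose phosphate pathway (0.32) and chaperones (0.31). The others were glycolysis (0.27), cytosolic ribosomal proteins (0.26), translation factors (0.23), the DNA damage response (−0.039) and cell cycle regulators (−0.42). In slope the 2 cultures differed in 8 lists: cell cycle regulators (0.29 log2 per 10 min), ribosomal proteins (0.25), oxidative phosphorylation (0.20), ergosterol synthesis (0.16), Gcn4 genes (−0.076), antioxidant defence (−0.16), the proteasome (−0.17) and general stress (−0.18). None of these 19 passed with an estimated correlation on the arrays as deposited (camera, 0 lists at an unadjusted p under 0.05), and ergosterol synthesis and the proteasome passed in slope on centred arrays. The relation of level and slope across genes was −0.376 under oxidative stress and 0.215 under DNA damage, with the same sign in both arrangements of the references in each; that difference was not tested. Among the 218 unnamed probe sets outside the comparisons, 2 stood above both references at time 0 by more than 2.09, the largest difference between the references, in each stress. The same probe set led in both, by 4.88 under oxidative stress and 3.22 under DNA damage, at 15.81 and 14.16 against 10.62 and 10.94 in the references. A gap test set an array apart in 0 of 20 groups.

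General stress transcripts rose after the shift although transcription was being stopped: the median rise from 0 to 15 min was 1.41 in reference 1, 0.86 in reference 2 and 0.91 under DNA damage, and 0.15 under oxidative stress, where the list started at 14.06 against 12.18 and 12.44 in the references. The smallest of the first 3, 0.864, lay above 0.460, the largest difference between technical arrays at time 0, which argues against array scaling as the whole cause there. Under oxidative stress the rise of 0.153 lay within that difference, so scaling stays open. Transcription that continued for the first minutes after the shift is a candidate explanation: relative to the median gene, the change from 15 to 30 min was at most 0.132 of that from 0 to 15 min in every culture. The heat shift was common to all 4 cultures, so stress from heat and incomplete arrest were not separated, and a lag in decay of the median gene was not tested.

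Genes higher at time 0 under oxidative stress tended to fall faster (r = −0.376 across genes). Dim probe sets alone do not account for it, since r was −0.401 in the brighter genes. Shared arrays are argued against as the whole cause, because r and the mean rank correlation of −0.258 come from separate arrays and references. The 2 arrangements gave r of −0.153 and −0.60, outside −0.0522 to 0.0574 in 100 simulations without effects. The rank correlation of the first, −0.0269, lay inside its simulated range. Reference 1 minus reference 2 gave −0.317, so the simulations do not cover spread between cultures. That spread stays open, as its covariance was −0.0204 against −0.0536 and −0.0164 for oxidative stress. A faster loss of induced transcripts under oxidative stress may be biological, but with 1 stressed culture it cannot be told apart from culture spread.

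Ribosomal protein transcripts fell faster under DNA damage (−0.31 relative to the median gene, 22 of 127 called and 105 not passing, 124 below the median gene), though the list's call was lost with an estimated correlation (adjusted p = 0.964, and adjusted p = 0.0529 on centred arrays). Brightness does not account for it, as the lowest of 10000 lists matched on brightness reached −0.0737, and the 102 members with a probe set of their own shifted by −0.341, so probe sets shared between copies do not carry it. The shift grew with time, from −0.25 at 10 min to −0.89 at 30 min relative to time 0. Reference 1 minus reference 2 shifted by −0.0147, but DNA damage was applied to 1 culture, so spread between cultures cannot be told apart from an effect of the stress. A stress effect on the stability of these transcripts stays a hypothesis.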

How the results depend on the processing

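The settings named above as added were chosen only after the data were seen. No paired analysis was possible for a single stress, as its 1 culture leaves no residual degree of freedom. A fit of both stresses, paired with the references by spike-in pattern, was not run. Order below: oxidative stress, DNA damage, direct comparison, then (slopes) reference decay. Level counts, 488, 234 and 324, became 148, 71 and 4 when centred, 88, 27 and 1 after quantile normalization, 201, 76 and 106 among the brighter genes, 1272, 1063 and 1973 with array scatter as the error (3023, 3162 and 2929 also centred, where reference 1 minus reference 2 gave 2598), 140 to 153, 29 to 38 and 3 to 35 without 1 time 0 array, and, with array scatter as the error as well, 721 to 2220, 879 to 1048 and 1590 to 2615 without 1 reference, to be set against the 1272, 1063 and 1973. Slope counts, 31, 71, 82 and 1233, became 0, 0 and 0 when centred, quantile normalized (1303 for reference decay) or over all time points (181, 988 and 861 at an unadjusted p under 0.05 by limma; 747 for reference decay), and 1, 0, 0 and 0 from 5 to 30 min (17, 62, 44 and 1215 unadjusted). On centred values eBayes found 2.43 prior degrees of freedom in place of infinity and a prior SD of 0.059 in place of 0.13; the cause of the lost calls was not tested. Without a filter reference decay gave 633, the brighter genes 20 for oxidative stress and 773 for reference decay, a trend in the prior 107 for DNA damage, and array scatter 206 for DNA damage and 182 for the direct comparison (425, 1452, 1417 and 2626 centred). Leaving out 1 time point gave 5 to 144, 47 to 623, 48 to 463 and 794 to 2074, and 1 reference, with array scatter as the error as well, 17 to 34, 102 to 237, 161 to 295 and 527 to 1312 (46, 206, 182 and 1433 with both references). Lists passing were 9, 11 and 11 in level and 5, 7, 8 and 10 in slope. With an estimated correlation 0 passed in all 6 stress comparisons (1 list unadjusted, in oxidative stress level). With it on centred arrays 3, 1 and 0 passed in level and 0, 1, 2 and 0 in slope. Reference 1 minus reference 2 passed 8 and 7 lists at the preset correlation (level, slope), and 1 and 0 estimated on centred arrays. Slope lists under oxidative stress numbered 8 when centred, 13 over all times and 9 against reference 1 on centred arrays. For named genes 3226 results kept direction and side, 696 lost and 122 gained a call, 140 without a test moved; for lists 491, 113 and 42. RPL3 (−0.0925) and NOP56 (−0.153) under oxidative stress lay below 0 on centred arrays with array scatter, as they do relative to the median gene, and above it as deposited (0.29 and 0.23): the sign rests on the centring, which moves all genes of an array alike. Other causes were not tested. Relations kept their sign (−0.632 to −0.383, and 0.139 to 0.234). Dim genes lie near the array floor, which limits fold sizes.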

Other observations

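The iron, mating, hypoxic and purine lists and all tests in this part were chosen only after the result was seen, including the allowance of 1 standard error and the removal of FIT2 and MRS4 from the iron test.

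Of 22 tested iron regulon genes, which Aft1 induces when iron is short, 10 rose at time 0 under oxidative stress and 12 did not pass (median shift 0.45, adjusted p = 1.4e-04, camera). Under DNA damage 5 rose and 17 did not pass (0.74, adjusted p = 4.4e-13), while reference 1 minus reference 2 shifted by −0.27. Every list called in this part lost its call with an estimated correlation (adjusted p = 0.897 each). As deposited ISU2, an iron-sulfur scaffold gene, differed by 3.29 and 2.50 log2. FMP23, at 10.63 in reference 1 and so below the filter, differed by 2.96 and 2.60. The mitochondrial iron carrier gene MRS4 differed by 2.49 and 2.34 and the siderophore transporter gene ARN1 by 1.27 and 1.81. Not all members rose: FET3 stood at −0.044 and −0.20 and FTR1 at −0.12 and −0.47, neither called. In slope the list shifted by −0.13 log2 per 10 min under oxidative stress (adjusted p = 7.7e-06). FMP23 and ISU2 were the 2 of 22 that fell faster, and reference 1 minus reference 2 shifted by −0.11. Of 18 purine synthesis genes at time 0 under DNA damage, ADE17, SHM2 and HPT1 fell, IMD2 rose and 14 did not pass. The list shifted by −0.28 (adjusted p = 0.0190). That shift was −0.40 against reference 1 and −0.13 against reference 2, which differed by 0.29, and IMD2 stood at 12.67 against 10.51 and 12.80, above reference 1 alone.

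Of 18 tested mating genes, FUS1, FAR1, AGA1, PRM1 and TEC1 fell at time 0 under oxidative stress, PRM5 rose and 12 did not pass (shift −0.62, adjusted p = 1.5e-08, and adjusted p = 0.897 with an estimated correlation), against a shift of −0.56 for reference 1 minus reference 2. Under DNA damage the list shifted by 0.11 (adjusted p = 0.548). Hypoxic genes shifted by −0.32 under oxidative stress (adjusted p = 0.0424, and adjusted p = 0.897 with an estimated correlation), where ANB1 and TIR1 fell, CYC7 and ROX1 rose and 7 of 11 did not pass. The shift was −0.082 against reference 1 and −0.45 against reference 2, and TIR1 stood at 11.45 against 11.33 in reference 1 and 14.24 in reference 2.

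A faster loss of iron regulon transcripts under oxidative stress was a hypothesis from FMP23 and ISU2. The other 18 members had a median slope difference of −0.0826 (standard error 0.0569) relative to the median gene, 13 of them below it, and −0.050 with FIT2 among them. With a bound of −0.1 set for the list, this decides neither way.

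Lower mating transcripts under oxidative stress were a hypothesis from FAR1, TEC1, PRM1 and FUS1. The other 14 members stood at −0.418 against reference 1 (standard error 0.127) and −0.873 against reference 2, which is in line with it. The references differed from each other by −0.514 in the same members, so a difference between cultures may account for it as well, and both stay open.

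ANB1, TIR1, IMD2 and ADH5 split the cultures by their spike-in pattern, and a difference in oxygen supply or growth between the pairs was a candidate explanation. The other 9 hypoxic genes differed by −0.220 between reference 1 and reference 2 and by −0.44 (standard error 0.33) between oxidative stress and DNA damage. These values do not settle it.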
